A study of Mus musculus with 15 samples.

How the data were processed

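SAM68 binding was measured by iCLIP2 in E14 mouse embryonic stem cells at day 0 and in embryoid bodies at day 3 and day 10, with 5 libraries per day according to the labels. Per the labels' protocols, cells were crosslinked with ultraviolet light of 254 nm at 150 mJ/cm2, embryoid bodies were dissociated into single cells before crosslinking, RNA was trimmed with RNase I to fragments of 50 to 200 nt, and adapters carried unique molecular identifiers, so that amplified copies can be told from separate molecules. The submitters' processing notes name FastQC 0.12.1, MultiQC 1.31, STAR 2.7.11a, UMI-tools 1.1.6, bedtools 2.31.1 and SAMtools 1.22.1 and the builds GRCm38.p5 and GRCh38.p14, without saying what each was used for. The program that called the sites, the filter for agreement between replicates and the way the 5 libraries of a day were combined are not given in the sources used here.

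The authors deposited 1 list of binding sites per day. Per the file headers, sites had been assigned to genes and those in overlapping genes removed. Each entry is a position of 5 nt on a strand with a site number, an Ensembl gene ID and a gene class. The score of every deposited site is 0, and per the file headers the score is switched off for display, so it was not used. The lists hold called sites only, without crosslink counts, so the depth of the libraries is unknown, a gene without sites has no floor, and for genes at 0 sites only the numbers are given. A difference in list length between days can come from depth, from the calling or from the amount of bound RNA, and ratios between days were therefore scaled by the length of each list.

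Gene symbols were assigned by position from a RefSeq gene table of GRCm38.p6, because its entries carry no Ensembl IDs. An ID took the symbol of the RefSeq gene of the same class whose span held at least 80% of its sites. In this way 7271 of 7949 IDs were named (91.5%), among them 7060 of 7380 protein-coding IDs, and 22 IDs that shared a symbol and 124 with several candidates stayed unnamed. As a check of the build, 98.9% of sites of protein-coding IDs lay inside a RefSeq protein-coding span, against 46.6% after a shift of 1 Mb. Coordinates in the text are those of the lists, counted from 1 at the centre of a site, and gene lengths are RefSeq spans.

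Site overlap was computed on the same strand with at least 1 nt shared, with exact binomial 95% intervals and 100 random placements within 10 kb windows that hold a site. Per gene, the ratio of shares between days has an exact conditional binomial 95% interval, and log2 ratios used a pseudocount of 1. The pseudocount was not scaled by list length, so genes with few sites are drawn towards negative log2 ratios for day 10 against the earlier days. A fold in the text is the ratio of shares without the pseudocount. Gene lists were compared through the median log2 ratio and its percentile among 10000 random lists of the same size matched on deciles of site number and of gene length. A list is called high or low beyond the outer 2.5% on either side. This describes the lists and is not a test between days. Tied medians were found by exact comparison, which misses ties that differ by rounding. Shares by length and position refer to sites in named protein-coding genes and have bootstrap intervals from 1000 resamples of genes, and shares by gene class have Wilson intervals. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

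The steps were tested on simulated data. Of the 1692 genes with at least 20 sites over the 3 lists, a subset was given simulated differences and the rest were left unchanged. For day 10 against day 0, 85% of the subset were called at a difference of 4 times and 37% at a difference of 2 times. Of the unchanged genes among the 1692, 4.56% and 3.15% were called. For day 3 against day 0 the recovered shares were 63% and 27.5%, and for day 10 against day 3 they were 86.5% and 46%. The simulated sites were drawn independently, as the exact interval assumes. Sites within a real gene are not independent, so the rate of false calls in the real lists is not measured by this. Of unchanged simulated lists, 4% to 7% were called. Where 10% or 30% of sites were copied into a second list, 10% and 30% were found. The copied sites kept their exact positions and the other sites of that list were moved to another chromosome. This checks the counting alone and not the overlap of shifted or clustered sites.

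The comparisons, the 13 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for each pair of days, the 10 genes with the largest and the 10 with the smallest log2 ratio among genes with at least 20 sites over both lists, the 5 genes with most sites per day, from each gene list up to 3 members with most sites and up to 2 with the largest log2 ratio in size for day 10 against day 0 among members with at least 10 sites, and every reported SAM68 target. Some genes that meet this rule are not reported here. Zfp42, Nanog, Tet2, Dnmt3a, Tbx20, Gata6, Mef2c, Ttn, Cacnb2, Col4a2, Lamb1, Cdh1, Rbpj, Slit2, Zeb2, Igf2r, Fgf5 and Otx2 were named in addition after their values had been seen, as were the members of symbol families in the closing section. Alternatives covered the overlap that counts as shared, strand, list length, merging of sites within 50 nt, at least 3 sites per gene, pseudocounts of 0.5 and 5, a minimum of 5 sites, another scaling and another matching. Enrichment of the A/U-rich motif, exon and intron classes and distances to splice sites need a genome sequence and exon annotation, which were not used here, so that gene classes and the position within the gene span stand in their place. Settings based on the score were left out because it is constant. Genes counted several times where they overlap were left out because the authors had removed such sites.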

Results

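SAM68 (Khdrbs1), an RNA-binding protein of the STAR family with roles in splicing and RNA processing, was mapped on its RNA targets by iCLIP2 in E14 mouse embryonic stem cells. In iCLIP2, ultraviolet light fixes the protein to RNA, an antibody recovers the complexes, and the nucleotide at the crosslink is read from the place where reverse transcription stops. Cells were taken as undifferentiated stem cells at day 0 and as embryoid bodies, aggregates in which stem cells differentiate into derivatives of the germ layers, at day 3 and day 10. Each day had 5 libraries, 15 in all, and the title of the series places the work in the formation of the heart. The question the design addresses is which RNAs SAM68 binds at each stage.

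The values analysed were 3 lists of binding sites, 1 per day, each site 5 nt wide and assigned by the authors to a gene. The day 0 list held 29740 sites in 5056 genes, the day 3 list 28266 sites in 5034 genes and the day 10 list 74287 sites in 6345 genes. The day 10 list was therefore 2.50 times as long as the day 0 list and 2.63 times as long as the day 3 list, and the median number of sites per bound gene was 4 on day 10 against 2 on day 0 and 2 on day 3. Because the lists carry no values for single libraries, the spread between replicates is unknown and no test between days was made. Intervals below are 95% intervals that cover counting error only, and sites within a gene are not independent. A gene's share is its number of sites divided by the length of that day's list. A gene is said to hold a larger or smaller share where the exact interval of the ratio of shares excludes 1. RNA abundance was not used here, so site numbers were not set against expression. Day 10 bodies were grown in spheroid plates from the start and day 3 bodies in hanging drops, so the day and the culture format cannot be told apart.

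Compared with the day 0 list, the day 10 list held few sites in transcripts of the pluripotency network and many in transcripts of cardiac, mesodermal, endodermal and matrix genes. In the day 0 list, Esrrb held 39 sites, Nr5a2 46, Tfcp2l1 35 and Zfp42 20, and in the day 10 list these 4 genes together held a single site, in Tfcp2l1. All 4 encode transcription factors of the naive stem cell state. In the opposite direction, Slc8a1, which encodes the sodium-calcium exchanger of heart muscle, held 439 sites on day 10 and none on day 0 or day 3. Gata4, a transcription factor of heart and endoderm, held 0, 4 and 111 sites on day 0, day 3 and day 10.

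**Figure D1:**
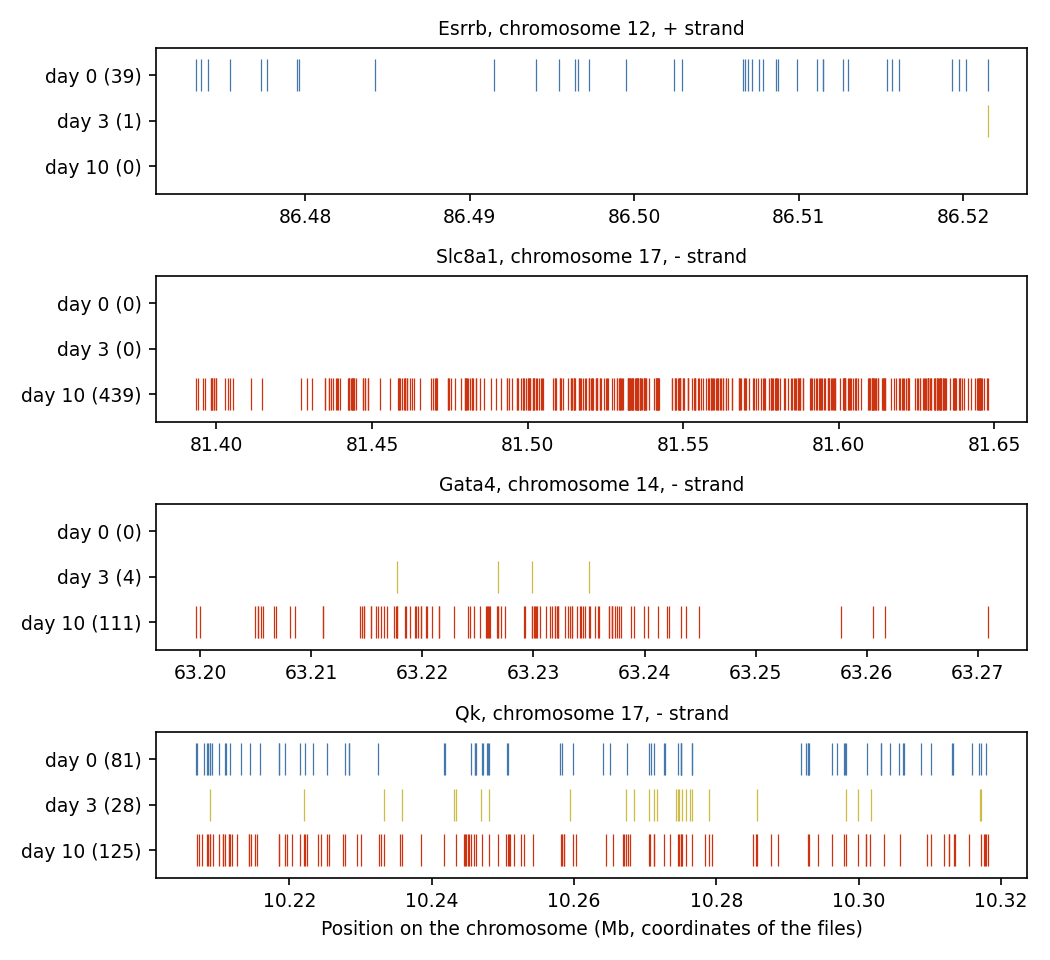
Positions of SAM68 binding sites in Esrrb, Slc8a1, Gata4 and Qk. Each vertical line is a binding site, the rows are the 3 days with the number of sites in brackets, and the horizontal axis is the position on the chromosome in Mb. Esrrb holds 39 sites on day 0 and none on day 10, Slc8a1 holds 439 sites on day 10 alone, Gata4 holds 111 sites on day 10 and 4 on day 3, and Qk holds sites on each day.

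The pluripotency list held 302 sites on day 0 and 131 on day 10, which is 102 and 17.6 sites per 10000 sites of the respective day. Of 23 members with a site on either day, 12 held a smaller share on day 10, 1 a larger share and 10 were open. The median log2 ratio of the list was -2.78, at percentile 0 of 10000 random gene lists matched on site number and gene length. Nanog, a core pluripotency factor, held 10 sites on day 0 and none on day 10. Tet2, an enzyme that oxidises methylated cytosine, held 37 and 8 sites, 0.0866 times the day 0 share (0.0348 to 0.189). Rif1, a telomere- and replication-associated protein, held 35 and 6 sites, 0.0686 times (0.0236 to 0.165). The member with a larger share was Dnmt3a, a de novo DNA methyltransferase, with 0 and 13 sites. Jarid2, a partner of the Polycomb repressive complex, held the most sites of the list on day 10, 51 against 35 on day 0, still 0.583 times its day 0 share (0.372 to 0.924).

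The list of mesodermal and cardiac transcription factors held 111 sites on day 0 and 1176 on day 10, 37.3 and 158 per 10000. Of its 22 members with a site, 10 held a larger share on day 10, none a smaller share and 12 were open, and the median log2 ratio was 1.18, at percentile 100. Zfpm2, a cofactor of GATA factors in heart development, held 144 sites on day 10, Tbx20 46, Gata6 33 and Mef2c 32, and none of these 4 genes had a site on day 0. Meis2 held 36 and 186 sites, 2.07 times its day 0 share (1.44 to 3.04). Tead1, an effector of the Hippo pathway, held 69 and 190 sites, and its ratio was open (interval 0.833 to 1.47).

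Sarcomere genes held 29 sites on day 0 and 288 on day 10, with a median log2 ratio of 0.68 at percentile 99.9. Of 23 members, 5 held a larger share on day 10, 1 a smaller share and 17 were open. Tpm1, which encodes tropomyosin, held 1 and 53 sites, 21.2 times the day 0 share (3.65 to 854). Palld, an actin-organising protein, held 62 sites on day 10 and Ttn, the giant protein of the sarcomere, 35, with none in either gene on day 0. Pdlim5, a protein of the Z-disc, held 5 and 46 sites, 3.68 times (1.47 to 11.9). The member with a smaller share was Dmd, the dystrophin gene, with 20 and 2 sites, 0.0400 times (0.00454 to 0.165). All Dmd sites of the 3 lists lay between positions 85057181 and 85202912 of chromosome X, within a gene that spans 2390 kb.

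Genes for calcium handling and ion channels held 20 sites on day 0 and 697 on day 10, and 439 of the latter lay in Slc8a1. Of 16 members, 6 held a larger share on day 10, 1 a smaller share and 9 were open, with a median log2 ratio of 1.43 at percentile 98.3. Ryr2, the calcium release channel of heart muscle, held 87 sites on day 10, Camk2d, a calcium-dependent kinase, 37 and Cacnb2, a subunit of voltage-gated calcium channels, 30, with none in these 3 genes on day 0. Without Slc8a1, the list's sites were 20 and 258, 5.16 times the day 0 share. The list's percentile was 94.5 among genes with at least 5 sites, short of the threshold for a high list.

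**Figure D2:**
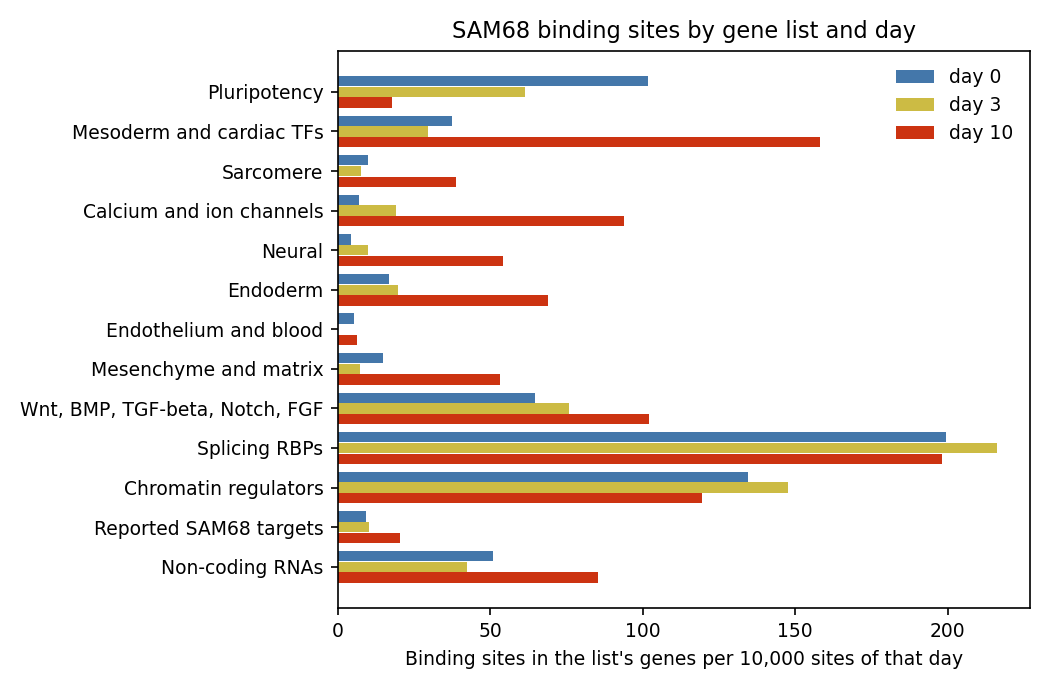
Binding sites in the genes of the 13 fixed lists, per 10000 sites of the same day. Bars stand for the 3 days and carry no error, because the lists hold no values for single libraries. The pluripotency list holds 102 on day 0, 61.2 on day 3 and 17.6 on day 10, the mesodermal and cardiac transcription factors hold 37.3, 29.4 and 158, and splicing proteins lie between 198 and 216.

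Matrix and mesenchymal genes held 44 sites on day 0 and 396 on day 10, with a median log2 ratio of 1.49 at percentile 100. Of 20 members, 8 held a larger share on day 10, 1 a smaller share and 11 were open. Ptn, the growth factor pleiotrophin, held 77 sites on day 10 and Fbn2, a fibrillin, 25, with none on day 0, and Vcan, the proteoglycan versican, held 3 and 63 sites, 8.41 times (2.75 to 41.9). The member with a smaller share was Fn1, fibronectin, with 34 and 29 sites, 0.341 times (0.201 to 0.577).

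Endoderm genes held 50 sites on day 0 and 513 on day 10, with a median log2 ratio of 1.13 at percentile 100. Of 18 members, 8 held a larger share, 1 a smaller share and 9 were open. Among the members with a larger share were Col4a1, with 0 and 87 sites, Col4a2, with 0 and 76, and Lamb1, with 0 and 45, which encode collagen and laminin chains of basement membranes. Dab2, an endocytic adaptor of visceral endoderm, held 0 and 80 sites. Cdh1, E-cadherin, held 13 and 14 sites, a smaller share on day 10. Restricted to genes with sites on both days, the endoderm list lay at percentile 74.2.

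Genes of the Wnt, BMP, TGF-beta, Notch and FGF pathways held 192 sites on day 0 and 759 on day 10, with a median log2 ratio of 1.00 at percentile 99.97. Of 30 members, 11 held a larger share on day 10, 2 a smaller share and 17 were open. Tcf7l2, a nuclear effector of Wnt signalling, held 1 and 93 sites, 37.2 times (6.52 to 1486), and its relative Tcf7l1, a repressor in stem cells, held 64 and 101 sites, 0.632 times (0.457 to 0.878). Bmpr1a, a BMP receptor, held 6 and 84 sites, 5.60 times (2.47 to 15.7). Rbpj, the DNA-binding effector of Notch, held 45 and 14 sites and was the other member with a smaller share. With a pseudocount of 5 the list lay at percentile 87.0.

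The neural list held 13 sites on day 0 and 402 on day 10, and its median log2 ratio of 0.90, at percentile 94.6, was inside the central range. Of 12 members, 5 held a larger share on day 10, 1 a smaller share and 6 were open. The 5 were Robo1, Robo2 and Slit2, receptors and a ligand of axon guidance, Cdh2, N-cadherin, which is also a cadherin of heart muscle, and Zeb2, a transcription factor of the neural crest. Robo2 held 149 sites on day 10, Cdh2 69 and Robo1 60, with none on day 0. The endothelial and blood list was thin on both days, with 16 and 47 sites, a median log2 ratio of -0.32 and percentile 62.1. Flt1, a receptor for VEGF, held 29 sites on day 10 and none on day 0, while Kit, a receptor of stem and blood progenitor cells, held 9 and 5 sites, 0.222 times (0.0586 to 0.739).

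Transcripts of splicing proteins held a similar share on day 0 and day 10, 593 and 1472 sites or 199 and 198 per 10000. Of 46 members, 6 held a larger share, 5 a smaller share and 35 were open, and the median log2 ratio of -0.15 lay at percentile 88.4. Among them, Rbm20, a splicing regulator of titin in heart muscle, held 0 and 25 sites, Celf2 0 and 46, and Mbnl2 39 and 185, 1.90 times (1.34 to 2.76). Qk, another STAR protein, held 81 and 125 sites, 0.618 times (0.463 to 0.828). Chromatin regulators held 400 and 888 sites, with 6 members at a larger share, 8 at a smaller share and 25 open, and lay at percentile 16.2. Nipbl, the cohesin loader, held 17 and 107 sites, 2.52 times its day 0 share with an interval above 1, and Ncor1, a corepressor, 62 and 32, 0.207 times (0.130 to 0.322). The non-coding RNA list held 151 and 633 sites and lay at percentile 71.4, with 6 members at a larger share, 1 at a smaller share and 6 open. Airn, the imprinted antisense transcript of the Igf2r locus, held 3 and 267 sites, 35.6 times (12.1 to 174), and Kcnq1ot1 75 and 158 sites, 0.843 times (0.637 to 1.13).

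Across all genes with a site on day 0 or day 10, 546 of 7451 held a larger share on day 10 and 780 a smaller share. Among the 1351 genes with at least 20 sites over both lists, 407 held a larger share, 264 a smaller share and 680 were open, and 153 had sites on day 10 only against 25 on day 0 only. The unequal list lengths shape these counts. A gene of the day 10 list alone passes this filter at a smaller share than a gene of the day 0 list alone. Without the filter, fewer sites were needed to call a smaller share than a larger one. Cecr2, with 3 sites on day 0 and none on day 10, held a smaller share, while Tek of the endothelial list, with none and 9, was open. The counts therefore do not show in which direction more genes changed, and the same holds for day 3 and day 10. The genes with the largest ratios outside the lists were Grip1, a synaptic scaffold protein, with 0 and 455 sites, Gpc3, a glypican of the cell surface, with 0 and 459, Rbms3, an RNA-binding protein, with 310, Arhgap6 with 298, Unc5c, a netrin receptor, with 291, and Pcdh7, a protocadherin, with 267. Tmem108 with 230, Nfia, a transcription factor, with 212, and Maml3, a Notch coactivator, with 263 completed the 10 that include Slc8a1. Gpc6, another glypican, held the most sites of any gene on day 10, 919 against 20 on day 0, 18.4 times its day 0 share (11.8 to 30.3), between positions 116927314 and 117975858 of chromosome 14. The smallest ratios belonged to Jam2, an adhesion molecule of cell junctions, with 82 sites on day 0 and none on day 10, Cobl, an actin nucleator, with 140 and 1, Bcat1, an aminotransferase of branched-chain amino acids, with 67 and 0, Sgcz with 65 and 0, Rnf17 with 51 and 0, and Fut9, Grik3 and Rims2, besides Esrrb and Nr5a2. Wwox held the most sites on day 0, 229, and 113 on day 10, 0.198 times (0.156 to 0.249). Scaled by list totals, the median log2 ratio of genes with at least 5 sites was -0.10 for day 10 against day 0 and -0.17 for day 10 against day 3. The sign depends on the filter, since for day 10 against day 0 the median was 0.16 among genes with at least 20 sites and -0.32 over all genes. It depends on the pseudocount too, because -0.32 is the value of a gene with no day 0 site and 1 day 10 site, such as Mtor. The sign of these medians therefore does not give the direction of change.

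Against day 0, the day 3 list held few sites in part of the naive pluripotency genes, and another set of genes held sites on day 3 and few or none on day 0 and day 10. Jam2 held 82 sites on day 0 and none on day 3, Sgcz 65 and none, Tfcp2l1 35 and none, Cobl 140 and 4 and Esrrb 39 and 1. Dnmt3b, a de novo DNA methyltransferase of the primed state, held 0, 20 and 0 sites on day 0, day 3 and day 10, and Fgf5 and Otx2, markers of the primed state, held 0, 19 and 0 and 0, 6 and 0. Adam23, a cell surface protein of the disintegrin family, held 0, 62 and 0 sites, Sulf1, a heparan sulfate endosulfatase, 0, 60 and 6, and Kcnq3, a potassium channel, 0, 31 and 0. Other genes with few or no sites on day 0 held sites on both later days. Grip1 held 90 on day 3 and 455 on day 10, Setbp1 51 and 66, Plxdc2 44 and 41, Aff3 27 and 33, Gpc3 25 and 459 and Robo1 24 and 60, all with none on day 0, and Slit3, a guidance ligand, held 1, 63 and 116.

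The pluripotency list held 302 sites on day 0 and 173 on day 3. Of 31 members, 4 held a larger share on day 3 (Dnmt3b, Fgf5, Otx2 and Jarid2), 7 a smaller share and 20 were open, and the median log2 ratio of 0.07 lay at percentile 51.5. Among members with at least 5 sites the list lay at percentile 0.16. High on day 3 were the calcium and ion channel list, with a median log2 ratio of 1.40 over 9 members at percentile 98.8, the endoderm list, with 1.66 over 11 members at percentile 99.9, and the signalling list, with 0.81 over 21 members at percentile 98.4. Within these lists few members stood apart on their own, with 2, 1 and 0 at a larger share and 1, 2 and 1 at a smaller share. Low were the mesodermal and cardiac transcription factors (-0.93, 7 members, percentile 0.64), with Meis2 at 36 and 1 sites and Tead1 at 69 and 21, the neural list (-1.51, 5 members, percentile 1.66), although its sites numbered 13 on day 0 and 28 on day 3 with 1 member at a larger and 1 at a smaller share, and the endothelial and blood list (-2.73, 3 members, percentile 0.02), which had no site on day 3. Of these 6 lists, the calcium and the endothelial list were the ones that stayed beyond the thresholds under a pseudocount of 5, and neural genes with at least 5 sites lay at percentile 65.1. With at least 5 sites the mesodermal and cardiac factors lay at 25.8 and endoderm genes at 79.2, and signalling genes with sites on both days lay at 95.7. Endoderm genes with sites on both days lay at percentile 3.22. The sarcomere, matrix, splicing, chromatin and non-coding lists lay at percentiles 18.4, 73.6, 71.1, 86.7 and 53.8.

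Among the 724 genes with at least 20 sites over the day 0 and day 3 lists, 122 held a larger share on day 3, 124 a smaller share and 478 were open. Exoc4, a subunit of the exocyst, was among the 5 genes with most sites on each day, with 143, 175 and 435 sites. Kat6b, a histone acetyltransferase, held 204 sites on day 0 and 40 on day 3, 0.206 times (0.143 to 0.291), and Abcc4, an efflux transporter, held 25 and 120, 5.05 times (3.26 to 8.11). Tex14, Cdyl2, Mme, Epha4, Ly75 and Dnajc6 held 47, 32, 31, 29, 26 and 26 sites on day 0 and at most 1 on day 3.

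Between day 3 and day 10, 6 of the 13 lists lay high and the pluripotency list lay low. The mesodermal and cardiac transcription factors held 83 and 1176 sites, with 12 of 22 members at a larger share on day 10 and none at a smaller share. Sarcomere genes held 21 and 288 sites, with 5 of 23 at a larger share and none at a smaller share. Matrix genes held 20 and 396 sites (9 of 20 at a larger share), endoderm genes 56 and 513 (9 larger and 3 smaller of 19), neural genes 28 and 402 (5 larger and 1 smaller of 11) and non-coding RNAs 120 and 633 (4 larger and 1 smaller of 15). Their medians of 1.57, 0.61, 1.46, 1.19, 1.19 and -0.07 on the log2 scale lay at percentiles from 98.96 to 100. The non-coding list kept its place under merging alone among the settings that can move it, with percentiles of 90.3 to 97.49 under the other 5. The neural list lay at 94.3 with a pseudocount of 5 and 96.4 when matched on length alone, and sarcomere genes with sites on both days lay at 85.3. The pluripotency list held 173 and 131 sites, with 9 of 28 members at a smaller share, 1 at a larger share, a median log2 ratio of -2.39 and percentile 0. Among members with at least 5 sites its percentile was 4.80, and among members with sites on both days it was 40.8, so that the call ended under both. The calcium, signalling, chromatin, splicing and endothelial lists lay at percentiles 85.6, 97.1, 7.03, 35.7 and 52.9.

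Among the 1311 genes with at least 20 sites over the day 3 and day 10 lists, 321 held a larger share on day 10, 229 a smaller share and 761 were open. Arhgap6, Rbms3, Slc8a1, Unc5c, Pcdh7, Tmem108, Nfia, Nrp1, Robo2 and Tanc2, the 10 genes with the largest ratios, had no site on day 3 and from 145 to 439 on day 10. Fut9, which makes the Lewis X stem cell antigen, held 37, 33 and 0 sites on day 0, day 3 and day 10, Grik3 36, 20 and 0, Rims2 35, 35 and 0, and Rnf17 51, 25 and 0. Cecr2, a bromodomain protein, held 3, 22 and 0 sites, Frmd5 7, 49 and 3, and the long non-coding RNA Platr22 5, 39 and 0.

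The list of transcripts reported elsewhere as SAM68 targets held few sites on day 0 and day 3, with 27 and 29, and 151 on day 10. Of 9 members compared between day 0 and day 10, 2 held a larger share, none a smaller share and 7 were open, at percentile 40.0. The 2 were Sgce, epsilon-sarcoglycan, with 0, 1 and 52 sites, and SAM68's own transcript Khdrbs1, with 5, 12 and 48 sites, 3.84 times its day 0 share on day 10 (1.54 to 12.4). Bcl2l1, whose splice forms encode opposing regulators of apoptosis, held 6, 2 and 22 sites, and its day 10 ratio to day 0 of 1.47 (0.577 to 4.43) was open. Eef1a1 held 8, 4 and 16 sites, Actb 4, 2 and 7, Cd44 2, 1 and 2, Smn1 1, 1 and 2, Mtor 0, 1 and 1 and Ccnd1 0, 1 and 0. Between day 0 and day 3 all 10 members compared were open, at percentile 82.6, and between day 3 and day 10 Sgce and Bcl2l1 held a larger share, with the list at percentile 52.0.

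Of the day 0 sites, 5160 overlapped a day 3 site on the same strand by at least 1 nt, or 17.4% (16.9 to 17.8), and 7178 overlapped a day 10 site, or 24.1% (23.7 to 24.6). Of the day 3 sites, 7325 or 25.9% (25.4 to 26.4) overlapped a day 10 site. Random placement within 10 kb windows gave 0.222%, 0.410% and 0.448%, so that the observed overlap was 78.3, 58.9 and 57.8 times the random one. Placement within the range of the gene's own sites, a control chosen after the data were seen, gave ratios of 11.1, 10.9 and 11.6. With each list thinned to the length of the shortest, the shares overlapping a day 10 site were 9.24% for day 0 and 9.93% for day 3. The share of day 0 sites overlapping a day 3 site was then 17.4%. Under random thinning, day 0 sites thus overlapped day 3 sites more often than day 10 sites, the reverse of the order in the full lists. Day 3 was the shortest list and kept all its sites, while day 10 sites were dropped at random, whatever their strength. The order therefore depends on how list length is treated, and the lists do not settle on which day more day 0 sites recurred. Of the day 10 sites, 9.68% overlapped a day 0 site and 9.90% a day 3 site, and 84.4% overlapped neither, as did 68.6% of day 0 sites with respect to the later days.

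**Figure D3:**
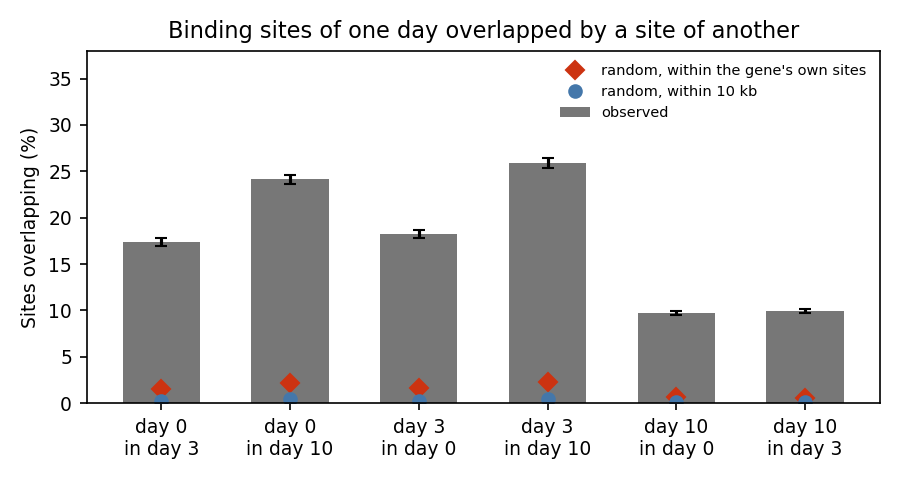
Share of the binding sites of a day that overlap a site of another day on the same strand by at least 1 nt, in percent. Bars are observed shares with exact 95% binomial intervals for counting error, circles the mean of 100 random placements within 10 kb windows and diamonds the mean of 100 placements within the range of the gene's own sites. Observed shares run from 9.68% to 25.9% and lie above both kinds of random placement.

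Of the genes bound on day 0, 3744 (74.1%) were also bound on day 3 and 3950 (78.1%) on day 10, and 4080 of the day 3 genes (81.0%) were bound on day 10. Among the 7949 genes bound on any day, independent lists would share 3202, 4036 and 4018. Among protein-coding genes, 3527, 3753 and 3871 were shared, where independent draws from the 21900 protein-coding genes of RefSeq would share 1015, 1286 and 1288. The first expectation is drawn from the lists themselves and leaves out genes bound on no day, which raises it. The second counts genes whether or not their RNA was present, which lowers it. Sites in all 3 lists were found in 3288 genes. Genes bound on 1 day alone numbered 650 on day 0, 498 on day 3 and 1603 on day 10. All these counts come from lists of unequal length. With each list thinned at random to the length of the shortest, 4966, 5034 and 4763 genes were bound on day 0, day 3 and day 10. Day 0 then shared 3696 genes with day 3 and 3182 with day 10, and day 3 shared 3351 with day 10. Jam2, Sgcz and Bcat1 were among the genes without a day 10 site, whereas Exoc4, Magi1, Etl4, Rbpms and Msi2 held at least 22 sites on each day.

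Listed sites lay almost entirely in protein-coding genes, with 95.3% (95.1 to 95.6) on day 0, 96.5% (96.3 to 96.7) on day 3 and 97.0% (96.9 to 97.2) on day 10. The lists hold only sites assigned to a gene, without those in overlapping genes, so these are not shares of all binding. Long non-coding classes held 3.45% (3.25 to 3.66), 2.69% (2.51 to 2.88) and 2.49% (2.38 to 2.60), with Kcnq1ot1, Neat1 and Airn among their members. Among sites inside the RefSeq spans of named protein-coding genes, the last 10% at the 3' side held 12.1% (11.4 to 12.7), 13.0% (12.4 to 13.7) and 10.8% (10.2 to 11.4) of sites on day 0, day 3 and day 10, and the first 10% held 8.90% (8.39 to 9.43), 9.66% (9.05 to 10.3) and 10.5% (9.96 to 11.1). Exons and introns could not be assigned with the reference used here.

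Among sites in the 7060 named protein-coding genes, the longest genes held a larger part on day 10. The longest 10% of these genes, with spans of 169 kb or more, held 20.8% of their day 0 sites (17.4 to 24.3, bootstrap over genes), 24.3% of day 3 sites (21.2 to 27.5) and 31.2% of day 10 sites (27.4 to 34.7). Gpc6, Rbms3, Exoc4, Grip1, Ryr2 and Slc8a1, with spans from 365 to 1057 kb, belong to this class, and so does Wwox, which held most sites on day 0. The shortest 10% held 3.28% (2.82 to 3.76), 3.81% (3.35 to 4.34) and 2.27% (1.99 to 2.57).

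**Figure D4:**
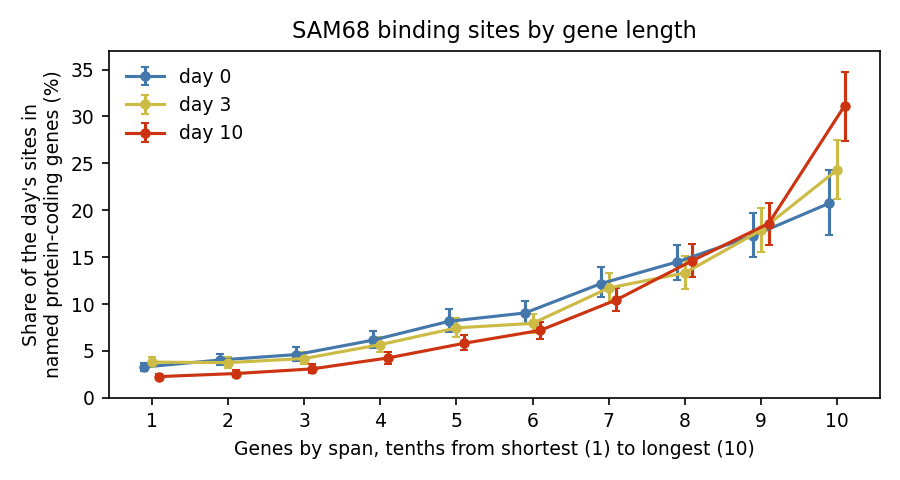
Share of the binding sites of each day in named protein-coding genes, in percent, by gene length in 10 classes of equal size from the shortest to the longest genes. Points are shares, lines join the points of a day and bars are 95% bootstrap intervals over genes. In the longest class the shares are 20.8% on day 0, 24.3% on day 3 and 31.2% on day 10.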

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

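The test of whether the missing site numbers belong outside the genes that keep sites was chosen after the result had been seen.

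Each site carries a running number, and the numbers reach 70573 on day 0, 69714 on day 3 and 137163 on day 10, far above the sites listed. They leave 40833 numbers without a listed site on day 0, 41448 on day 3 and 62876 on day 10, so that 42.1%, 40.5% and 54.2% of numbers have one. These stand out because they point to sites that none of the comparisons use.

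If the missing numbers belonged to sites outside the genes that keep sites, few would lie between neighbouring listed sites of the same gene, but 47.2% of those missing on day 0 did (44.1 to 50.4), as did 51.6% on day 3 and 65.4% on day 10. Removal of sites in overlapping genes, the step the file headers name, would place missing numbers in intervals that touch another gene, and 15.3% of those missing inside named genes on day 0 lay in such intervals (13.9 to 16.7), where 9.37% of all intervals touch another gene. Both values argue against these steps as the whole cause. A filter on strength or on agreement between replicates stays open and was not tested, and no biological explanation was tested.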

How the results depend on the processing

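The placement of random sites within a gene's own range, the restriction to genes with sites in both lists and a tolerance for tied medians were chosen after the data had been seen. No paired analysis was possible because the lists carry no values for single libraries, so that no replicate was left out either. Settings on the score, on sites in several genes, on exon and intron classes, on the motif and on splice-site distances were not run.

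Day 10 against day 0, 6 high lists and 1 low list were the counts, and every setting run left them within 1.5 times. The calcium list lay at percentile 94.5 with at least 5 sites and 87.6 among genes in both lists, the endoderm list at 74.2 among the latter, and the signalling list at 87.0 with a pseudocount of 5. The neural list was high, at 97.7, with a pseudocount of 5, and splicing proteins, at 98.2, when matched on length alone. Day 3 against day 0, the 3 high lists became 1 with a pseudocount of 5 and 1 among genes in both lists, in both cases the calcium list. Matched on length alone, 2 lists were high and 2 low. The signalling list then lay at 96.7 and the mesodermal and cardiac factors at 4.76. Low lists numbered 3, and 1 with a pseudocount of 5, the endothelial list. They numbered 1 with at least 5 sites and 1 among genes in both lists, but there the low list was pluripotency (0.16 and 0.045) and none of the 3 kept its call. The mesodermal and cardiac factors lay at 25.8 and 36.3, the neural list turned to 65.1 and then had too few genes, and the endothelial list had too few genes under both. The endoderm list turned to 3.22 among genes in both lists. Day 10 against day 3, the low list was lost (0 lists) with at least 5 sites and among genes in both lists, where fewer genes were compared. The 6 high lists became 4 with a pseudocount of 5, 4 when matched on length alone and 4 among genes in both lists, as the non-coding list lay at 97.0, 96.5 and 97.49 and the neural list at 94.3 and 96.4 under the first 2. Among genes in both lists the sarcomere list lay at 85.3, the neural list had too few genes for a value, and the reported targets were high at 99.2. The non-coding list also lay below the threshold with a pseudocount of 0.5 and with at least 5 sites (both 90.3), where the signalling list (99.7 and 99.1) took its place. Centring on the median gene adds the same value to every gene and so leaves the order of lists as it is. The shift of the sarcomere list from 18.4 to 20.0, day 3 against day 0, came from rounding of tied medians. With a tolerance for ties, centring moved 0 of 39 percentiles, while 11 differed from those given, by up to 3.10, and 0 calls differed. Centring moved ratios by 0.07 to 0.17 in size on the log2 scale, and none of 279 ratios of named genes counted as moved or reversed. A pseudocount of 5 moved 91 of the ratios and reversed none. Among the 6 lists high for day 10 against day 0, it made the sarcomere, endoderm, signalling and matrix medians negative, at -0.58, -0.33, -0.47 and -0.06. The medians of the mesodermal and cardiac factors and of the calcium list stayed positive, at 0.14 and 0.05. Percentiles are against random lists under the same pseudocount. Of the 39 list calls, 37 were the same with a pseudocount of 0.5, 31 with 5, 38 after merging and 34 when matched on length alone. The same held for 30 of the 38 lists left with at least 5 sites and 24 of the 34 left among genes in both lists.

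With at least 50% reciprocal overlap, 16.0%, 22.2% and 24.0% of sites were shared (day 0 in day 3, day 0 in day 10, day 3 in day 10), and with a gap of up to 50 nt 22.3%, 31.5% and 33.6%. Thinned lists gave 9.24% and 9.93% for the pairs with day 10, since fewer day 10 sites remain to be met. Against placement in the gene's own range the ratios were 11.1, 10.9 and 11.6. With at least 3 sites, 2524, 2474 and 3856 genes were bound on day 0, day 3 and day 10, and 1730, 1926 and 2030 were shared, because fewer genes qualify. Merged sites lay to 97.2% in protein-coding genes on day 10. Of other moves the cause was not tested.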

Other observations

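Chosen only after the result was seen were the symbol families, the test with a gap of up to 50 nt, the comparison with random positions, the limit set by the number of day 10 sites, and, in the tests among genes in all 3 lists and without 20 genes, the demand that the whole interval lie beyond the bound. Without these stricter readings, 3 explanations left open below would have counted as supported: a few genes with very many sites, incomplete recovery, and sites left out of the list.

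Several gene families defined by their symbols, some with members in the fixed lists, held many sites on day 10. Unless another pair of days is named, family percentiles are for day 10 against day 0. The glypicans Gpc3, Gpc4 and Gpc6, which carry heparan sulfate at the cell surface, held 20, 66 and 1381 sites on day 0, day 3 and day 10, with 919 of the day 10 sites in Gpc6, at percentile 94.5 of matched random lists. Collagen genes held 2, 20 and 231 sites, of which Col4a1 and Col4a2 of the endoderm list held 87 and 76 on day 10, with 5 of 13 members at a larger share on day 10 than on day 0 and none at a smaller share, at percentile 99.99. The Robo, Slit, Unc5 and Ntn genes of axon guidance, among them Robo1, Robo2 and Slit2 of the neural list, held 11, 103 and 711 sites. Day 10 against day 0, 6 of 8 members held a larger share and 1 a smaller share, at percentile 99.3. Day 10 against day 3, 3 members held a larger share, 1 a smaller share and 4 were open, at percentile 53.0. Cadherin genes held 17, 36 and 284 sites at percentile 48.9, with Cdh11 at 96 day 10 sites, Cdh2 of the neural list at 69, Cdh3 at 52 and Cdh6 at 52. Ephrins and their receptors held 31, 9 and 275 sites, at percentile 93.3, but without Efna5 the numbers were 31, 2 and 64, a pooled share on day 10 of 0.827 times that on day 0.

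On the other side, the Platr genes, long non-coding RNAs named for their link to pluripotency, held 38 sites on day 0, 55 on day 3 and none on day 10. Of 6 members, 5 held a smaller share on day 10 than on day 0, at percentile 0, and 39 of the day 3 sites lay in Platr22. Genes with a Zfp symbol, mostly zinc finger proteins, held 842, 572 and 1180 sites, or 283, 202 and 159 per 10000, with 29 of 165 members at a smaller share and 7 at a larger share on day 10, but their median lay at percentile 32.8. Semaphorins and plexins held 7, 18 and 100 sites, at percentile 92.4.

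Among sites in named protein-coding genes, the share in the longest 10% of genes was higher on day 10 than on day 0 by 10.4 percentage points (6.13 to 14.4). One candidate explanation is that genes listed on day 10 and not on day 0 are longer. Their median span was 34.9 kb, 1.36 times the 25.6 kb of genes listed on day 0 and not on day 10, with an interval above 1. The difference thus had the predicted direction. Both medians lie below 37.5 kb, where the 6th of the 10 length classes begins, and the longest class begins at 169 kb. The test therefore cannot tell how much these genes add to the longest class. A longer list that recovers more sites in long genes of any kind stays open, since among 3037 genes with sites in all 3 lists the difference was 3.96 points (-0.53 to 8.69), an interval that includes the bound of 50% of the difference over all genes. A few genes with very many sites stay open for the same reason, since without the 20 genes with most day 10 sites the difference was 4.44 points (1.52 to 7.78). The stage of differentiation and the culture format remain as untested explanations.

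Of day 0 sites, 24.1% had an overlapping site on day 10. The tables argue against genes without day 10 sites and against small offsets as the whole cause, because 28.1% of day 0 sites recurred in the 561 genes with at least 10 sites in both lists (26.6 to 29.7) and 31.5% of all day 0 sites did so with a gap of up to 50 nt (30.2 to 32.7). Incomplete recovery stays open: the recurring share was 4.48 times higher (3.87 to 5.27) in genes with most day 10 sites per day 0 site than in those with fewest, 36.9% against 8.25%, which passes the bound set beforehand, but the number of day 10 sites caps the lower share at 25.3%. Sites called on day 10 and left out of the list stay open too: 58.6% of non-recurring day 0 sites between 2 day 10 sites of their gene (56.9 to 60.3) lay where day 10 numbers were missing, above the bound of 50%, but random positions in the same genes did so in 65.8%. A shift of binding within transcripts between days was not tested.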
